A study of Rattus norvegicus with 12 samples.

How the data were processed

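RNA was measured by sequencing of poly(A)-selected transcripts in primary vascular smooth muscle cells grown out of explants of the thoracic aortic media of male Sprague-Dawley rats (spelled Sprague-Dailey in the labels). Per the labels' protocols, cells at passage 4 were exposed overnight to adenovirus, grown to 75% confluence and kept in 0.2% serum for 24 to 32 h. The 12 libraries form 4 groups of 3, taken from the sample titles: a virus carrying green fluorescent protein (Ad-GFP), a virus overexpressing Cklf1 (Ad-Cklf1), a virus carrying a scrambled short hairpin RNA, and a virus carrying a hairpin against Cklf1. Both hairpin groups were also treated with tumour necrosis factor alpha (TNF) at 25 µg/L for 24 h, per the labels' protocols. The protocols describe DNase treatment, oligo(dT) selection, random-hexamer priming and Illumina sequencing. They mention no step that marks the strand. The labels call the samples triplicates without saying whether they came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

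Each deposited file gives 1 value per Ensembl transcript for 29330 transcripts, in the same order in all 12 libraries. The unit was read from the files as FPKM, fragments scaled to transcript length and to the fragments of the library: the file header uses the column name written by the Cufflinks tools, and the deposited values are decimals that sum to between 492242 and 627410 per library. The submitters' processing notes name the genome build Rnor 6.0. The aligner, the quantifier, the annotation release and any scaling between libraries are not given in the sources used here. FPKM per transcript is an estimate that divides reads among the isoforms of a gene. A transcript can therefore go from a value near 0 to a high one when reads are assigned to another isoform, and transcripts of 1 gene are not independent.

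The files pair the transcript identifiers with no gene names. The gene table used here, with 47357 genes on the GRCr8 assembly, holds no Ensembl identifiers, and 0 of the transcript identifiers matched it. Results are therefore given by transcript identifier, and the position, exon structure and gene of a transcript are not reported here. For the same reason 22 gene lists, with 386 symbols, and the tests planned for them were not run, and the Cklf gene was not identified in the files.

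The number of reads per library is not recorded in FPKM values. Many low values lie near steps that 1, 2 or 3 reads would give, and these steps were used for a rough estimate of relative depth. For transcripts between 0.001 and 0.1 FPKM in both libraries, the most frequent ratio to Ad-GFP replicate 1 was taken as the inverse of the relative depth. Between 53.5% and 60.1% of these values lay within 0.02 log2 units of that ratio times a ratio of whole numbers up to 3. The steps were thus centred on the most frequent ratio of the same values. The share that would lie there without steps was not computed, so this share does not check the estimate. No read counts could be derived for well expressed transcripts, whose read value depends on an unknown length, so no counting intervals are given.

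The planned design assumed counts and named a fallback for normalized values, which was used. Values were transformed to log2(FPKM + 1). The 13698 transcripts with a mean of at least 1 FPKM over the 12 libraries were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 12 libraries in 1 fit and 8 residual degrees of freedom. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low transcripts. A transcript was called when its Benjamini-Hochberg adjusted p was below 0.05 within a comparison, and 4 comparisons were made. These were Ad-Cklf1 against Ad-GFP, shRNA Cklf1 against scramble (both with TNF), the difference between these effects, and scramble with TNF against Ad-GFP. The rule for naming took, per comparison of a manipulated group with its control, the 8 largest log2 fold changes in each direction among called genes with a symbol, a mean of at least 1 and the 3 libraries of one group all above or all below the 3 of the other, and members of the gene lists. Without symbols it was applied to transcripts, and the first 2 per direction are named in each of these comparisons.

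The test was checked on simulated data built from the mean of each transcript over all libraries and its residual spread, with independent noise. Far fewer transcripts were changed in the simulation than were called in the data. The threshold on unadjusted p was therefore stricter there, and the rates below need not hold for the real comparisons. With 50 of 13698 transcripts simulated per fold size in the overexpression comparison, it recovered 64% of rises and 58% of falls of 0.5 log2 units, and 80% and 78% of those of 1 log2 unit. In the knockdown comparison it recovered 64% and 56% at 0.5, and 84% and 94% at 1. Of the unchanged transcripts 0.037% were called in the first and 0.0667% in the second. Replicates of a group shared at most 0.175% identical values among the tested transcripts, so no library was counted as a copy of another.

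This rule and the first set of alternatives were fixed before the data were examined. These alternatives were a pseudocount of 0.1, no filter on low values, only the 6 libraries compared, the replicate number as a block, leaving out each library, a minimum absolute log2 fold change of 1 and, for the relation of the effects, a filter at a mean of 10. Median-of-ratios and upper-quartile scaling, a filter at a mean of 10 FPKM for the 4 comparisons, one at 100 FPKM for the relation, and limma with a trend and a robust prior were added after seeing the data. The planned tests of read counts, and the scalings planned inside them, were not run, because the values are not counts. For the transcripts that fell by at least 1 log2 unit with overexpression, 10000 random sets of the same size were drawn from the other tested transcripts, matched in 5 bins of mean log2 level and 5 bins of residual standard deviation. For the count of such falls, unchanged groups were simulated in 20 runs around the Ad-GFP means, with the residual spread of each transcript and the measured Ad-GFP libraries kept. GC content and transcript length were not examined, since neither is in the files. Figures were drawn with matplotlib 3.10.9.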

Results

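The transcriptome was profiled in rat aortic smooth muscle cells given adenovirus meant to raise or lower CKLF1, a chemokine-like factor. The level of its gene was not checked here, because the files do not name genes. The series set out to describe how expression responds to up- and downregulation of this factor. Overexpression was compared with a virus carrying green fluorescent protein in serum-starved cells. Knockdown was compared with a scrambled hairpin in cells that were also exposed to TNF, a cytokine that activates inflammatory genes in vascular cells. Each of the 4 groups held 3 libraries. The estimated relative depth was highest in the Ad-GFP libraries, at 1.00, 0.98 and 1.29 for replicates 1 to 3. It was 0.83, 0.76 and 0.72 in Ad-Cklf1, 0.62, 0.66 and 0.65 in scramble, and 0.61, 0.70 and 0.76 in knockdown. Between 8164 and 9735 of the 29330 transcripts were listed at 0 in a library. Each library had between 13391 and 13634 transcripts above 1 FPKM. This number was 13589 to 13634 in Ad-GFP and knockdown, and 13391 to 13560 in Ad-Cklf1 and scramble. The upper quartile of FPKM split the groups in the same way, at 8.863 to 8.993 against 8.683 to 8.751.

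The 4 groups separated from each other. Libraries of a group correlated at 0.974 to 0.985 over the 13698 tested transcripts on the log2 scale, Ad-Cklf1 with Ad-GFP at 0.972 to 0.975, and knockdown with scramble at 0.961 to 0.971. The lowest values, 0.913 to 0.938, were between the arm without TNF treatment and the arm with it. The first principal component held 54.8% of the variance and separated the arms. The second held 12.9% and separated the groups within each arm, with Ad-GFP and knockdown on one side and Ad-Cklf1 and scramble on the other. The median standard deviation between replicates was 0.088 log2 units in Ad-GFP, 0.078 in Ad-Cklf1, 0.091 in scramble and 0.109 in knockdown. Knockdown replicate 3 stood apart from its group, at 23.8 on the first component against 31.2 and 30.6.

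**Figure D1:**
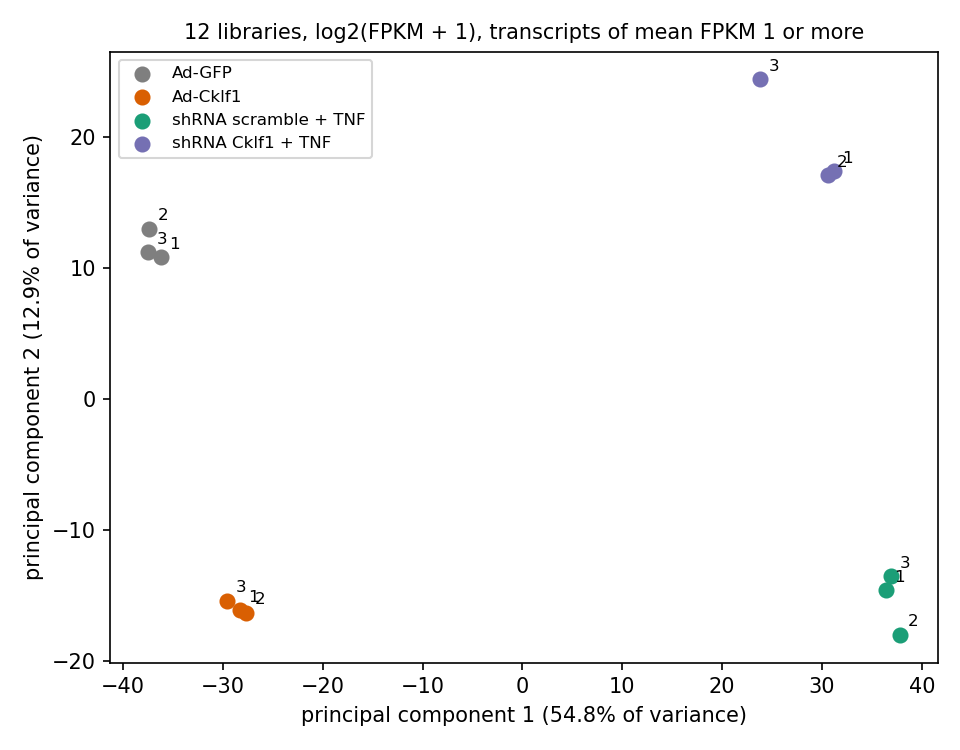
Scores of the 12 libraries on principal components 1 and 2 of log2(FPKM + 1), in component units, with 54.8% and 12.9% of the variance. Points are libraries, colours are groups and digits are replicate numbers; Ad-GFP lies between -36.2 and -37.5 on component 1 and scramble between 36.4 and 37.8.

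The largest rise between Ad-GFP and Ad-Cklf1 among called transcripts, on the log2(FPKM + 1) scale, was that of ENSRNOT00000017127. It rose from 5.59 ± 1.15 FPKM (SD, n = 3) in Ad-GFP to 3158 ± 323 FPKM (SD, n = 3) in Ad-Cklf1, a ratio of means of 565. Its log2 fold change was 8.91 (SE 0.23, limma adjusted p = 9.94e-09). The same transcript fell in the knockdown, from 4.59 ± 1.61 FPKM to 1.44 ± 0.441 FPKM (SD, n = 3 each), with a log2 fold change of -1.16 (SE 0.23, limma adjusted p = 0.00401). The files do not name its gene, so these values do not establish that it is the targeted transcript. In scramble and in Ad-GFP its level did not pass the test for a difference (log2 fold change -0.27, SE 0.23, limma adjusted p = 0.326).

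Beyond that transcript, many transcripts differed by small amounts between Ad-Cklf1 and Ad-GFP. In Ad-Cklf1, 1068 transcripts rose and 1514 fell against Ad-GFP, which is 18.8% of the 13698 tested (limma, adjusted p below 0.05). The median size of a called change was 0.33 log2 units, a fold of 1.26 on the log2(FPKM + 1) scale. The large changes were mostly falls: 64 transcripts fell by at least 1 log2 unit and 8 rose by as much. The next largest rise by the naming rule was that of ENSRNOT00000079460, which was near 0 in the 3 Ad-GFP libraries and at 3.09, 2.81 and 1.5 FPKM in Ad-Cklf1 (log2 fold change 1.76, SE 0.41, limma adjusted p = 0.0168; 4.62 with a pseudocount of 0.1). ENSRNOT00000004278 fell the most, from 228, 117 and 164 FPKM in Ad-GFP to at most 0.270 FPKM in any Ad-Cklf1 library (log2 fold change -7.24, SE 1.03, limma adjusted p = 0.00179). It was also at or below 0.165 FPKM in the 3 scramble libraries and at 26.5, 0.0026 and 0.00173 FPKM in the knockdown. ENSRNOT00000081924 fell from 73.4 ± 4.47 FPKM to 2.96 ± 0.589 FPKM (SD, n = 3 each), with a log2 fold change of -4.24 (SE 0.10, limma adjusted p = 6.62e-09). Its level was 0.986 ± 0.125 FPKM in scramble and 2.06 ± 0.0609 FPKM in knockdown (SD, n = 3 each), both also below Ad-GFP. Of the 64 transcripts that fell by at least 1 log2 unit, 57 were also lower in scramble than in Ad-GFP and 43 were lower in both TNF-treated groups, where independent lists would share 19.6 and 13.5. The same 3 Ad-GFP libraries enter these comparisons, which favours such overlap. Unchanged groups simulated against them gave 0 falls of that size in any of 20 runs. The simulation therefore held no set in which an overlap could be counted, so the overlap that shared libraries alone would give is not known. The groups did not overlap for 99.6% of the 2582 called transcripts, and for 42.4% of all tested ones, where chance gives 10%. The counts depended on single libraries. Without Ad-GFP replicate 2 they were 578 rises and 997 falls, without Ad-GFP replicate 3 490 and 874, without Ad-Cklf1 replicate 1 555 and 1000, and without Ad-Cklf1 replicate 2 473 and 911; without Ad-Cklf1 replicate 3 the rises numbered 660. The call of ENSRNOT00000079460 was lost in those first 4 fits (limma adjusted p between 0.0503 and 0.06, from a range of 0.00472 to 0.06 over all alternatives). The share of rises among called transcripts was 41.4% as deposited and 52.9% after upper-quartile scaling, so which direction held more of the small changes depended on the scaling.

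In the knockdown comparison under TNF, many transcripts also moved by small amounts. Against scramble, 2195 transcripts rose and 1866 fell, which is 29.6% of those tested (limma, adjusted p below 0.05), with a median called change of 0.35 log2 units. After upper-quartile scaling 1976 rose and 2074 fell, so which direction held more of the changes depended on the scaling. Here the large changes were mostly rises: 150 transcripts rose by at least 1 log2 unit and 37 fell by as much. ENSRNOT00000081645 rose the most, from 0.00603, 0.0457 and 0.0384 FPKM in scramble to 4, 8.93 and 12.1 FPKM in knockdown (log2 fold change 3.07, SE 0.72, limma adjusted p = 0.0102). With a pseudocount of 0.1 its log2 fold change was 5.90. It also varied widely within Ad-GFP, at 0.02851, 9.225 and 0.8289 FPKM, and was at 2.51, 2.146 and 0.6855 FPKM in Ad-Cklf1. ENSRNOT00000085701 was at 0.0995, 6.07 and 0.0352 FPKM in scramble and at 15.0, 14.5 and 6.68 FPKM in knockdown (log2 fold change 2.63, SE 0.75, limma adjusted p = 0.0249; 4.38 with a pseudocount of 0.1). ENSRNOT00000056704 fell the most, from 34.3, 82.7 and 37.4 FPKM to 16.8, 0.0298 and 0.0917 FPKM (log2 fold change -4.16, SE 1.11, limma adjusted p = 0.0193). ENSRNOT00000086232 fell from 8.02 ± 1.69 FPKM to 0.962 ± 0.952 FPKM (SD, n = 3 each), with a log2 fold change of -2.30 (SE 0.53, limma adjusted p = 0.0101). None of these 4 transcripts passed the test in the overexpression comparison (limma adjusted p between 0.551 and 0.99). Of the direct tests of the difference between the effects, that of ENSRNOT00000081645 passed (limma adjusted p = 0.038), and those of the other 3 transcripts did not (limma adjusted p between 0.0558 and 0.185). The groups did not overlap for 98.2% of the 4061 transcripts called in the knockdown, and for 42.4% of all tested. A fit of the 6 hairpin libraries alone called 1373 rises and 1072 falls. Without knockdown replicate 3, which stood apart, 1968 rose and 1631 fell. The call of ENSRNOT00000085701 was lost in the fit of 6 libraries, without the filter on low values, and without scramble replicates 1 or 3 or knockdown replicates 1 or 2 (limma adjusted p between 0.0533 and 0.0851, from a range of 0.00295 to 0.0851 over all alternatives). That of ENSRNOT00000056704 was lost in the fit of 6 libraries and without scramble replicate 2 or knockdown replicates 2 or 3 (limma adjusted p between 0.0603 and 0.0677, from a range of 0.00203 to 0.0677 over all alternatives).

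**Figure D2:**
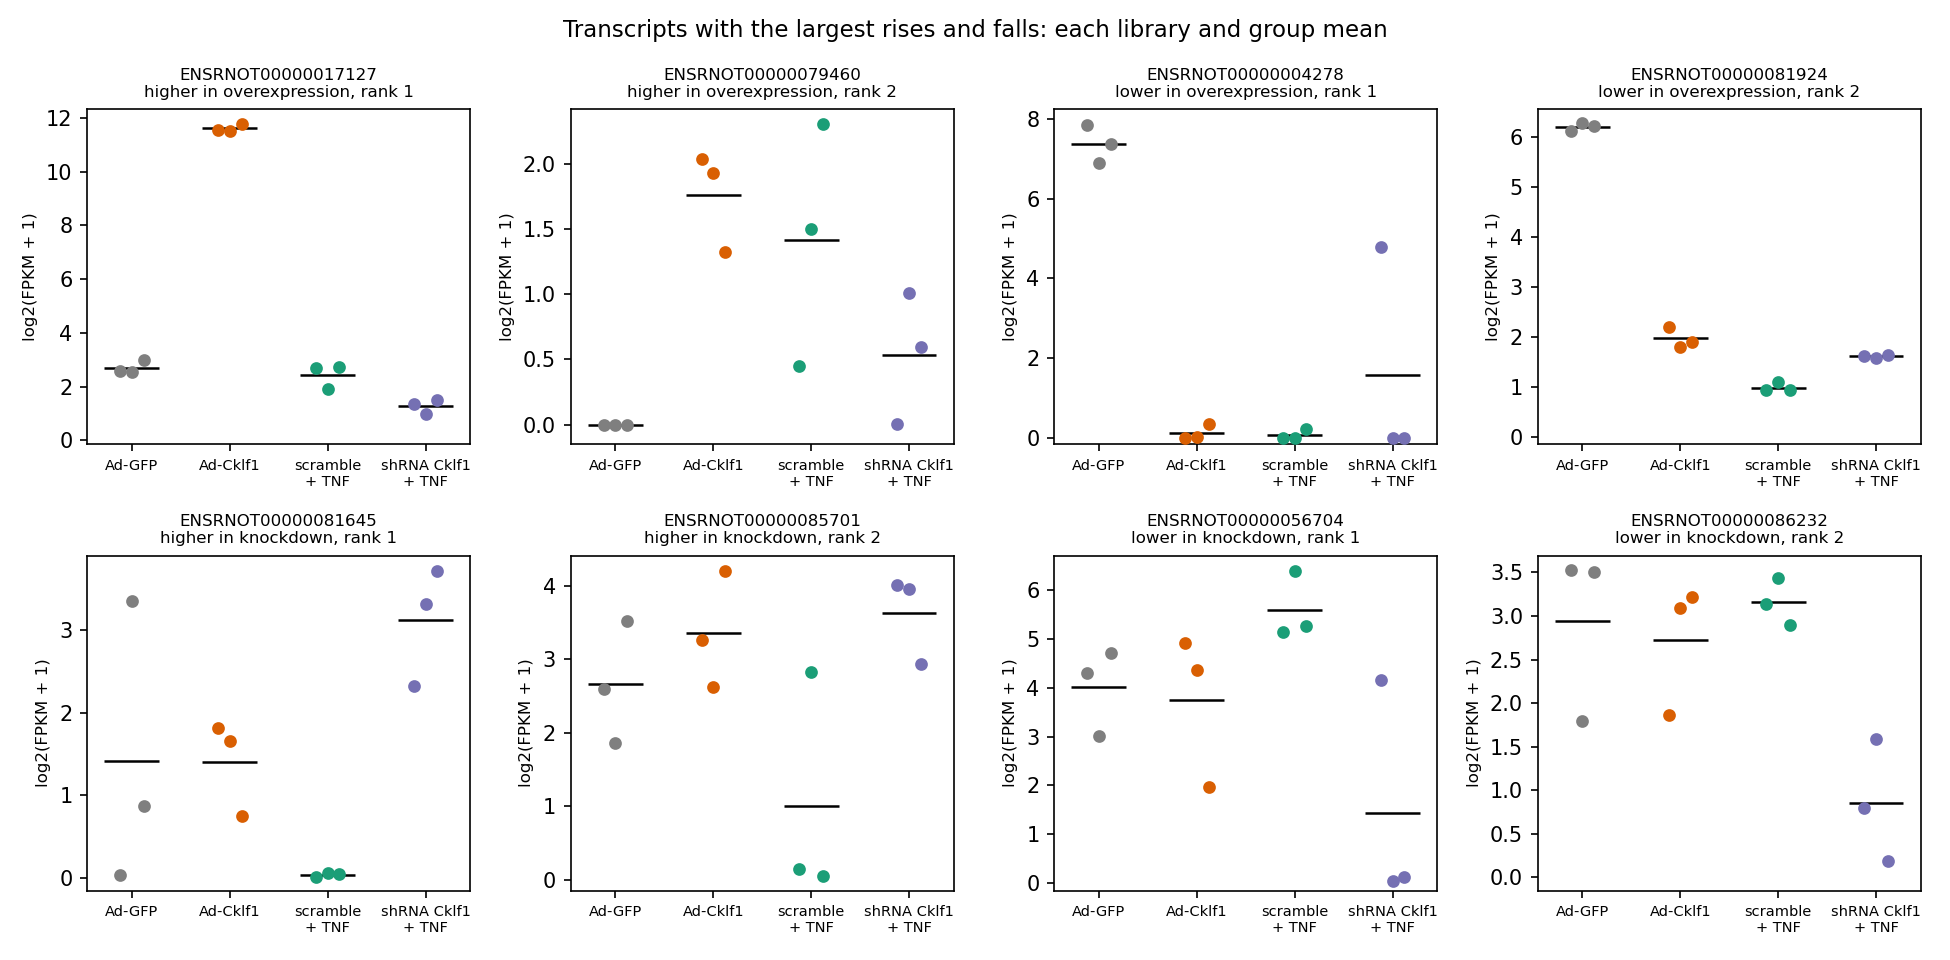
Level of the 8 named transcripts as log2(FPKM + 1) in the 4 groups. Points are libraries (n = 3 per group) and bars are group means of the log2 values; the upper row holds transcripts named for overexpression and the lower row those named for knockdown. ENSRNOT00000017127 stands above all other groups in Ad-Cklf1, at 3158 ± 323 FPKM (SD, n = 3).

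The transcripts called in both the overexpression and the knockdown comparison differed mostly in opposite directions. Of 1287 transcripts called in both comparisons, 1177 (91.5%) had opposite directions and 110 the same direction. In detail, 715 fell with overexpression and rose with knockdown, where independent lists of these sizes would share 243, and 462 rose with overexpression and fell with knockdown, where independent lists would share 146. Higher in both comparisons were 61 transcripts (171 for independent lists), and lower in both were 49 (206 for independent lists). Over all tested transcripts the 2 sets of log2 fold changes correlated at r = -0.34 (Pearson) and rho = -0.398 (Spearman). These are correlations across transcripts, which are not independent replicates, and the comparisons share no library. The comparisons do share the residual spread of each transcript, and calls were rarer at low levels in both. Shared calls of either direction are thereby favoured, so the numbers for independent lists are a rough reference. Unchanged groups simulated with the same spreads gave a mean r of 0.011. Their noise was drawn independently for each transcript and library, so an r near 0 was built in. Other splits of the measured libraries gave an r as far from 0 as 0.308.

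The difference between the effects was tested directly per transcript: overexpression minus knockdown was higher for 2190 transcripts and lower for 2639 (limma, adjusted p below 0.05). After upper-quartile scaling the counts were 2602 higher and 2286 lower, so which direction held more also depended on the scaling. The largest difference was that of ENSRNOT00000017127, at 10.08 log2 units (SE 0.32, limma adjusted p = 9.04e-08). The arms also differed in TNF treatment, so the difference compares the manipulations in those settings. The number of opposite calls fell to 695 without Ad-GFP replicate 3, 768 without Ad-Cklf1 replicate 1 and 704 without Ad-Cklf1 replicate 2. The number of same-direction calls was 56, 44, 68, 57 and 65 without Ad-GFP replicates 2 or 3 or Ad-Cklf1 replicates 1, 2 or 3, in that order.

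**Figure D3:**
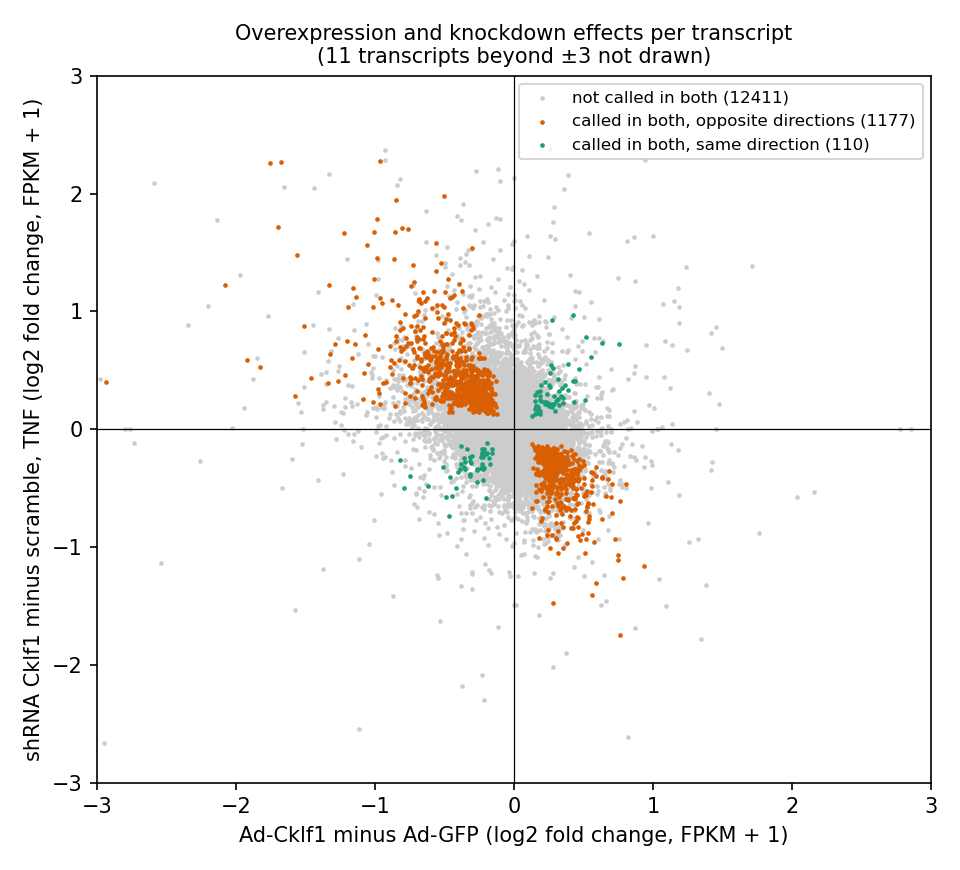
Log2 fold change of each tested transcript with overexpression (horizontal) and with knockdown under TNF (vertical), on the log2(FPKM + 1) scale; 11 transcripts beyond 3 log2 units on either axis are not drawn. Orange points are the 1177 called in both with opposite directions, green points the 110 called in both with the same direction, and grey points all others.

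The control groups differed in most of the tested transcripts. Scramble with TNF had 3948 transcripts higher and 4188 lower than Ad-GFP, which is 59.4% of those tested (limma, adjusted p below 0.05), with 530 higher and 767 lower by at least 1 log2 unit. TNF, the insert of the virus and any batch of the arm changed together in this comparison, so it describes the backgrounds and not TNF alone. Ad-Cklf1 differed from Ad-GFP mostly in the direction in which scramble with TNF did: of 2113 transcripts called in both, 1860 had the same direction. The knockdown comparison mostly ran against that difference: of 3282 transcripts called in both, 2888 had opposite directions. Each of these pairs shares 3 control libraries. The covariance of the fold changes was 0.104 for the first pair and -0.112 for the second, and unchanged groups simulated against the same controls gave 0.0187 and -0.0185. The correlations, 0.473 and -0.473, were no larger than the 0.497 and -0.494 that unchanged groups gave. Over all tested transcripts, directions were opposite for 31.98% in the first pair and 71.43% in the second. Unchanged groups gave 33.31% and 66.63%. Part of the overlap of calls may come from the shared libraries and from the residual spread that all comparisons share. Independent lists would share 308 rises and 463 falls for the first pair, where 697 and 1163 were seen. For the second they would share 538 transcripts higher in scramble and lower in knockdown than in scramble, where 1352 were seen. They would share 671 lower in scramble and higher in knockdown than in scramble, where 1536 were seen. The controls were not split, because 3 libraries leave fewer than 2 in one part.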

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

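The planned tests of read counts, and the scalings planned inside them, were not run on FPKM values, and the gene list tests were not run for lack of gene names. Scaling by median ratios or upper quartiles, limma with a trend and a robust prior, the filter at 10 FPKM for the 4 comparisons and the one at 100 FPKM for the relation were chosen after seeing the data. The named transcripts and r of the relation kept their sign under the alternatives tried. The replicate block, the filters, the fit of 6 libraries and the trend leave the fold change of a transcript unchanged by construction. Those settings could not change the sign of a named transcript. The block and the trend likewise could not change r, and the scalings could hardly do so. A pseudocount of 0.1 moved log2 fold changes from 1.76 to 4.62 (ENSRNOT00000079460), from 3.07 to 5.90 (ENSRNOT00000081645) and from 2.63 to 4.38 (ENSRNOT00000085701), as it shrinks low values less. Falls grew too, from -7.236 to -9.94 (ENSRNOT00000004278, overexpression), from -4.156 to -5.985 (ENSRNOT00000056704, knockdown) and from -2.297 to -3.411 (ENSRNOT00000086232, knockdown). A pseudocount of 0.1, no filter, the replicate block, both scalings and the trend left each count of the 4 comparisons and of the relation within 1.5 times. The replicate block, which rests on numbers that did not pair the samples (same-numbered libraries correlated at -0.048 to 0.074 in their deviations, and 6 of 12 did best with their own number), gave 1053 rises and 1477 falls for overexpression and 2199 and 1831 for knockdown, and changed none of the calls of named transcripts. Upper-quartile scaling shifted the median of all transcripts by 0.027 log2 units for overexpression and turned the majority direction in 3 comparisons: the share of rises went from 41.4% to 52.9% for overexpression and from 54.1% to 48.8% for knockdown, and that of higher transcripts from 45.4% to 53.2% for the difference. Among changes of at least 1 log2 unit it gave 9 rises and 58 falls for overexpression and 147 and 39 for knockdown. Requiring a log2 fold change of at least 1 left 8 rises and 64 falls for overexpression, 150 and 37 for knockdown, 167 and 507 for their difference, and 530 and 767 for the control groups. A fit of only the 6 libraries compared gave 1373 and 1072 for knockdown, and 1059 and 1606 for overexpression; the cause of the drop for knockdown was not tested. A filter at 10 FPKM tested fewer transcripts and gave 1758 lower for the difference and 2249 and 2577 for the control groups; for the relation it gave r = -0.405, 1055 opposite and 128 same-direction calls. At 100 FPKM the relation had r = -0.482, 140 opposite and 25 same-direction calls among 754 transcripts. Leaving out each library gave 473 to 957 rises and 874 to 1320 falls for overexpression, 695 to 1181 opposite calls and 44 to 144 same-direction calls; the ranges for knockdown (1697 to 1968 and 1401 to 1654) stayed within 1.5 times. The extreme overexpression counts came without Ad-Cklf1 replicate 2 (473) and Ad-GFP replicate 3 (874), and the cause was not tested. In those fits a group of 2 is assumed to vary like the others. ENSRNOT00000017127, ENSRNOT00000004278 and ENSRNOT00000081924 (overexpression) and ENSRNOT00000081645 and ENSRNOT00000086232 (knockdown) passed the threshold under every alternative run. Calls were fewer at low levels: 11% of those at 1 to 5 FPKM were called for overexpression against 26.7% of those above 100 FPKM.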

Other observations

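The tests at 100 FPKM, of split pairings under other settings, of a property of the Ad-GFP libraries and of the origin of ENSRNOT00000017127 were chosen only after the result had been seen. Among the transcripts at least 1 log2 unit higher in scramble with TNF than in Ad-GFP, 207 of 530 were lower in knockdown than in scramble and 74 were higher still. Among the 767 that were lower by as much, 378 were higher in knockdown than in scramble and 8 were lower still. The scramble libraries enter both comparisons, which by chance favours moves back toward Ad-GFP and works against the 74. Leaving out each of the 12 libraries gave 61 to 77 transcripts that were higher still and 4 to 11 that were lower still. The difference between these shares was not tested, since transcripts are not independent.

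The calls were spread over the expression range. For overexpression, 28.9% of the called transcripts at 1 to 5 FPKM were rises, against 49.5% of those at 20 to 100 FPKM and 44.3% of those above 100 FPKM. For knockdown the shares were 54.2%, 55.4% and 50.7%. After upper-quartile scaling they were 37.6%, 60.9% and 60.3% for overexpression and 50.8%, 50% and 45.3% for knockdown. ENSRNOT00000091327, singled out after its values were seen, ranged from 22.4 to 123400 FPKM and varied widely within groups. It was at 22.4, 410 and 1839 FPKM in Ad-GFP and at 34960, 13430 and 114300 FPKM in scramble, all higher (log2 fold change 7.18, SE 2.16, limma adjusted p = 0.0155). It was at 16200, 1318 and 15550 FPKM in Ad-Cklf1 and at 447, 123400 and 1823 FPKM in knockdown, and neither comparison of these groups with their controls passed the test (limma adjusted p = 0.154 and 0.329). It held the largest value in the files, and the total of all other transcripts stayed between 490419 and 505054 FPKM per library.

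The transcripts called in both the overexpression and the knockdown comparison differed mostly in opposite directions, and 3 simple accounts of this were examined. Of the 100 pairings of the 10 splits of each arm, 1, the real one, gave a Pearson r as far from 0 (-0.34, highest other 0.308). A chance split is therefore unlikely there, by a small margin. As far from 0 were 2 of 100 at 10 FPKM (-0.405, highest other 0.423) and 4 of 100 at 100 FPKM (-0.482, highest other 0.603). The real pairing was thus not the strongest at either filter. The groups differ in estimated depth, which would act on low transcripts, and r was not weaker at 100 FPKM (-0.517 to -0.424 when each library was left out). At that level another pairing of splits reached 0.603, so variation between libraries can give an r of that size without the real grouping. The value at 100 FPKM therefore does not settle whether depth contributed. Without knockdown replicate 3, which stood apart, r was -0.267 (highest other 0.253), so that library is not the whole cause. Effects of Cklf1 on these transcripts, a shift of the Ad-GFP libraries in transcripts that the knockdown also moves, or a culture state that differed between virus preparations in both arms, may each account for the pattern, and the design does not separate them. The number of transcripts above 1 FPKM and the upper quartile of FPKM also set Ad-GFP and knockdown apart from Ad-Cklf1 and scramble. After upper-quartile scaling r was -0.341. That scaling divides each library by 1 factor, which shifts most transcripts nearly alike, so r could hardly change. The value therefore does not bear on whether this split of the groups contributed. Whether a technical difference between libraries lies behind the pattern was not tested.

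Most of the 64 transcripts that fell by at least 1 log2 unit in Ad-Cklf1 were also lower in both TNF-treated groups (43, against 13.5 for independent lists), counted against the same Ad-GFP libraries that chose them. Of the 64, 54.7% rose with knockdown and 0 fell, against 16% rising among all tested transcripts and at most 26.6% in 10000 random sets matched on mean level and spread, which treat transcripts as independent. The 64 thus rose with knockdown more often than sets of similar level and spread. Leaving out each library gave 43.5% to 59.4%, but the falls of that size were chosen anew in each of these fits. The matched sets were drawn for the 64 of the full fit alone. Among falls of any size, 715 of 1514 transcripts also rose with knockdown. The matched sets were drawn whatever their direction with overexpression, so the test repeats the opposite relation described above. It is no separate evidence against a property of the Ad-GFP libraries, and one in transcripts that the knockdown also moves stays open. ENSRNOT00000081924 was 73.4 FPKM in Ad-GFP and at most 3.62 FPKM in any other library, and an effect of the control virus, of its cultures or of Cklf1 could each give such values, since Ad-GFP is the single control without TNF treatment.

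A hypothesis is that ENSRNOT00000017127 is the product of the overexpression construct. It rose by 8.91 log2 units and ENSRNOT00000079460, the next by the naming rule, by 1.76, and these were 9.13 and 4.62 with a pseudocount of 0.1. The log2 fold change of ENSRNOT00000017127 in the knockdown was -1.16, with 3 of 3 libraries lower than any of scramble (limma adjusted p = 0.00401). This is consistent with the hypothesis, but 1866 transcripts fell in the knockdown, and no identifier ties the transcript to Cklf.

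Other splits of the libraries called few transcripts. For overexpression the real split called 2582 and the highest other 1; for knockdown 4061 and 3; for the control groups 8136 and 0. In each, 1 of 10 splits reached the real count, and 10 splits cannot give a share under 0.05. For the difference of the effects, 1 of 100 drawn splits, the real one, called as many as 4829 transcripts, and the highest other called 1113. A chance split of the libraries is therefore unlikely there.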
